A study of Mus musculus with 18 samples.

How the data were processed

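Gene expression was measured on a small 2-colour muscle array in single fibers of the flexor digitorum brevis (FDB), a short foot muscle, taken from CD-1 mice of 4 to 5 weeks. Per the labels, the fibers were kept for 3 days in medium with 10% serum and 50 ug/ml gentamicin at 37 °C and 5% CO2, RNA came from more than 100 fibers per sample, and the amplified sample RNA carried Cy3 while a reference sample carried Cy5 on every array. By the labels no array had swapped dyes, so a dye effect that is the same on every array drops out of differences between groups. The labels call KN93 and KN62 inhibitors of the CaMK (calcium/calmodulin-dependent kinase) pathway and KN92 their inactive control compound; doses and the details of the electrical stimulation are not given in the sources used here.

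The 36 scanner files hold, per the file headers, spot intensity from quantification software version 5.5, with a signal and a local background for each of 144 spots per array. The deposited table made by the authors holds a linear ratio of sample to reference for 132 spots in each of 18 columns. Set against the scanner values, 16 columns followed Cy3 over Cy5 of the background-subtracted signal medians of their own array, times 1 factor per array, with a median absolute difference of 0.03 to 0.11 on the log2 scale. In 9 of the 16 the empty cells were, on all 132 cells, those with a signal at or below the background in either channel. In 6 more, 128 to 131 of the 132 cells followed that rule, and the column of stimulated KN93 replicate 2 was unfiltered and held 9 negative values. Column medians lay between 0.77 and 1.55, and how the factor of each array was set is not known. The direction of the table is therefore sample over reference, on a linear scale.

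The files give no gene names: the gene column of the scanner files is empty and the rows of the deposited table carry numbers only. The files do not pair these with genes. The 132 spots form 22 features of 6 spots each, in line order of the deposited table, numbered here from 1 to 22 in that order. The 2 triplets of spots of a feature tracked each other across features on every array, with a lowest correlation of 0.91 in the Cy3 channel. At most 2 features that were higher and 2 that were lower are given per comparison. The 18 gene lists and the single genes chosen before the data were examined matched 0 features, so the tests of gene lists and the centring on housekeeping genes were not run.

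The scans labelled stimulated KN93 replicates 1 and 2 are of 1 array: both headers name the same image, the spot coordinates were the same, and log2 Cy3 signals differed between spots by an SD of 0.08, against 0.48 for the next closest pair of arrays. Their mean was used as 1 replicate, leaving 17 arrays and 2 replicates of stimulated KN93 fibers. The spot grid of both scans was shifted by 1 column: their signals correlated with the other arrays at 0.96 after moving the grid by 1 column and at 0.15 as deposited. The grid was moved, which leaves feature 4 without a value on that array. The deposited ratios of these 2 columns follow the unmoved grid. The deposited column of unstimulated KN62 replicate 3 follows the scan filed under stimulated KN62 replicate 3 (0.05 on the same measure of difference, against 0.39 for its own scan), and the column of stimulated KN62 replicate 3 follows none of the 18 scans closely. The files were kept under their labels. For unstimulated KN92 replicate 3 and stimulated KN62 replicate 2, the title and source name give the group used here while the treatment text gives the other stimulation state.

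Signal and background medians were corrected with normexp (offset 50), and log2 ratios were normalized by loess within each array in limma 3.58.1 under R 4.3.3. The 12 spots outside the 22 features had no weight in the loess. Spots of a feature were averaged where at least 2 had a value. One linear model with 6 group means was fitted to the 17 arrays with lmFit, 12 contrasts were tested with eBayes, and p-values were adjusted by Benjamini-Hochberg over the features tested, with a threshold of 0.05. All 22 features were tested in every comparison. The rule for named features, fixed before the data were examined, takes every feature past the threshold. Where a comparison has none, it takes the most extreme log2 changes as values only. It allowed more of them than the 2 highest and 2 lowest used here, and had no background filter. Features not above background on any array of a group compared are passed over there, which was not part of that rule. In KN62 stimulation this leaves out feature 6, the highest of the 22 at 0.37. A feature counted as above background on an array when over 50% of its spots had a Cy3 signal median above the local background median. Feature 1 had a Cy3 signal median of 65000 or more on up to 6 spots of 10 scans, but not on most of its spots on every array of any group. The states were not alike in this: it had 6 such spots on stimulated KN92 replicates 1 and 2 and 0 on unstimulated KN92 arrays. With KN62 such spots occurred in both states. In the Cy5 channel up to 6 spots of a scan reached this limit. The stimulation changes of feature 1 are open to this. Bounds for features seen in only one of 2 groups were computed on the Cy3 channel after loess and Aquantile normalization, which stays open to dye bias without swapped arrays.

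The number of arrays limits the precision. On data simulated with the real groups and spreads, in 100 sets with 4 of 22 features changed, a change of 1 on the log2 scale was called for 77.5% of changed features in the KN92 stimulation comparison, 93.5% in the mean over compounds and 60.8% in the difference between KN62 and KN92. Because loess follows the features themselves on so small an array, a doubling of the sample signal was also planted into the stimulated scans, 1 feature at a time for 12 features: loess returned a median log2 change of 0.76 (0.21 for the brightest feature, 0.82 for feature 9) and median centring 0.87.

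Experiment numbers in the titles tie a stimulated to an unstimulated array of the same compound, so they were taken as pairs within a compound; KN93 experiments 1 and 2 share their stimulated array and formed 1 block. Deviations from the group means correlated with a median of 0.54 over the 9 pairs of the same experiment, from -0.31 to 0.88, and of -0.27 over the 15 other pairs. Deviations within a group sum to 0, so positive values in the former push the latter below 0, and the contrast is partly built in. For KN92 the pairs of the same experiment were at -0.31, -0.20 and 0.13. The 10 image folders named in the headers were tested as batches. Alternatives covered background correction, normalization, the spot summary, dim features, the deposited ratios, blocks, the variance model, left-out arrays and, added after seeing the data, the signal mean, the unmoved grid, the repeated scan as 2 replicates, a turned sign for 1 array and sets of arrays in doubt. Python 3.11.15 was used to read the files.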

Results

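RNA of cultured mouse FDB fibers was compared across 3 compounds, with and without electrical stimulation in a pattern of the slow fiber type. The title of the series asks whether fibers transform under stimulation without the CaMK pathway. Unstimulated fibers had 3 arrays with each of KN92, KN93 and KN62. Stimulated fibers had 3 arrays with KN92, 3 with KN62 and 2 with KN93, since the scans of stimulated KN93 replicates 1 and 2 came from the same array and were counted as 1 sample. The series describes its replicates as independent experiments. The array reported 22 features of 6 spots, whose genes are not named in the files.

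Signal over background set what could be read. The median Cy3 signal of an array lay between 1152 and 2708 units, and 84 to 113 of its 132 spots were above the local background (of 126 on the array with the moved grid). Features 3 and 13 were not above background on any of the 17 arrays, and 11 features were above it on all 17. The residual SD of the log2 ratio between replicates had a median of 0.25 over features and ranged from 0.08 to 1.07. Over the 136 pairs of arrays, log2 ratios correlated across features with a median of 0.07, and 13 pairs lay under -0.3. The lowest value was -0.66, between stimulated KN93 replicate 3 and stimulated KN62 replicate 3. The dyes stated in the labels were kept, with Cy3 as the sample. Stimulated KN62 replicate 3 also ran against both other arrays of its own group, at -0.52 and -0.46, so its direction is not settled. Cy3 over Cy5 of its scan followed a deposited column, that of unstimulated KN62 replicate 3, at 0.05. The authors' ratio thus has the direction used here, which does not test the labelling itself. With the sign of stimulated KN62 replicate 3 turned, none of the 12 counts of called features moved.

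The reference channel was not alike on all arrays. Feature 2 had a quantile-normalized log2 Cy5 signal of 13.20 to 13.90 on 4 arrays, the KN93 replicate 3 pair and the KN62 replicate 1 pair, and of 9.11 to 10.89 on the other 13. Its Cy3 signal overlapped between these sets, at 11.22 to 12.83 and 9.80 to 11.57. Across all features the log2 ratios of these 4 arrays correlated with each other at a median of 0.67 and with the other 13 at a median of -0.0048 (across 22 features, which are not independent replicates). Feature 2, by which the 4 arrays were set apart, is among these features, so part of the agreement may follow from that choice. The labels describe each array as part of a reference design of 2 arrays and do not say whether the experiments shared a reference. These 4 are called arrays with a differing reference below, a name that rests on the Cy5 signal of feature 2. With KN62 such arrays are 1 of 3 stimulated and 1 of 3 unstimulated ones. With KN93 they are 1 of 2 and 1 of 3. In the main fit, a difference between references therefore does not cancel in the KN93 stimulation difference or in the mean of the 3 compounds. It also stays in the comparisons of KN93 or KN62 with KN92, at rest and under stimulation, and in differences of stimulation effects with KN93. In KN93 minus KN62 at rest and in the KN62 minus KN92 stimulation effect such arrays are balanced in number. There it cancels only as far as it is equal on these arrays. With the experiment as a fixed replicate block, both arrays of such a pair lie in 1 block. A reference difference shared by the pair then cancels from the stimulation effects.

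**Figure D1:**
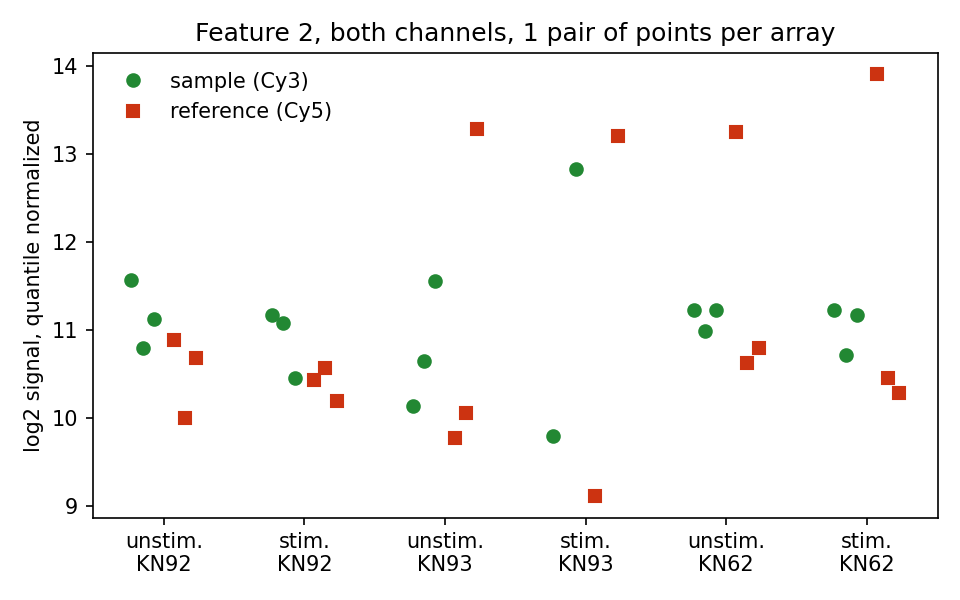
Quantile-normalized log2 signal of feature 2 in the sample channel (Cy3, circles) and the reference channel (Cy5, squares), with 1 circle and 1 square per array in each of the 6 groups. The reference signal lies at 13.20 to 13.90 on 4 arrays and at or below 10.89 on the other 13.

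The first question was which features stimulation changed, taking the 3 compounds together. Feature 9 fell by 0.36 on the log2 scale (SE 0.09, 95% interval -0.56 to -0.16) in the mean of the 3 stimulation differences, with an adjusted p of 0.0369 by limma. It was the 1 feature of 22 past the threshold, and 3 had an unadjusted p under 0.05. Its mean log2 ratio was 0.12 ± 0.16 (SD, n = 3) in unstimulated and -0.26 ± 0.13 (n = 3) in stimulated KN92 fibers, and 0.37 ± 0.22 (n = 3) against -0.18 ± 0.12 (n = 2) with KN93. With KN62 it was 0.32 ± 0.26 (n = 3) against 0.17 ± 0.12 (n = 3). The feature was above background on all 17 arrays, and 8 of 8 stimulated arrays lay below the unstimulated mean of their compound. Under median centring in place of loess the change was -0.19 with an adjusted p of 0.375, and the call ended. It was kept without unstimulated KN93 replicate 2, KN92 replicate 1 or KN62 replicate 2, or without stimulated KN92 replicate 2 or KN62 replicate 2. It was lost without any one of the other 12 arrays, with a change between -0.40 and -0.32 throughout. Within the image folders that hold both states it was -0.54 and -0.65 for KN93, -0.19 and -0.55 for KN92 and 0.20 for KN62. With the image folder as a block the change was -0.24 with an adjusted p of 0.313. Without the 4 arrays with a differing reference it was -0.32 (95% interval -0.53 to -0.11) with an adjusted p of 0.142, and the call ended. With the experiment as a replicate block, feature 9 and feature 8 both passed, with log2 changes of -0.37 and 0.35 and an adjusted p of 0.0141 each. In the sample channel alone, the change of feature 8 in the mean of the 3 compounds was -0.155 (adjusted p 0.850). Its sign turned there, but the 95% interval of -0.62 to 0.31 holds changes in both directions.

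**Figure D2:**
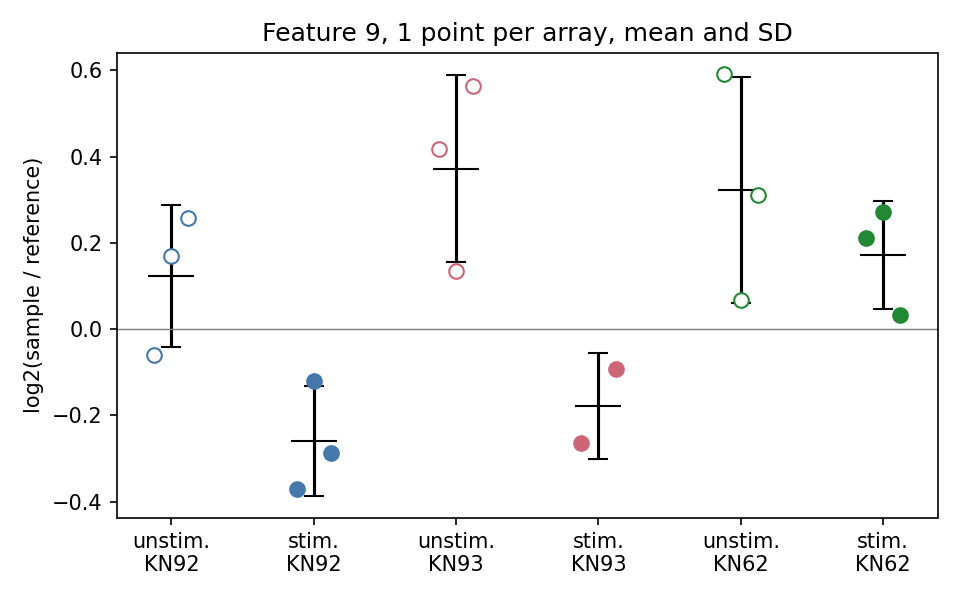
Log2 ratio of sample to reference of feature 9, 1 point per array (open, unstimulated; filled, stimulated) with the mean and SD of each group. With KN92 the stimulated mean is -0.26 against 0.12, with KN93 -0.18 against 0.37, and with KN62 0.17 against 0.32.

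In fibers with KN92, the inactive control compound, stimulation is read without CaMK inhibition. No feature of 22 passed the threshold by limma, and 2 had an unadjusted p under 0.05. Feature 8 was the highest, at a log2 change of 0.52 (SE 0.23), with group means of -0.35 ± 0.21 and 0.17 ± 0.04 (SD, n = 3 each) and an adjusted p of 0.471. Feature 10 followed at 0.33 (SE 0.19). Feature 9 was the lowest at -0.38 (SE 0.15) and feature 12 was at -0.35 (SE 0.26). Without stimulated KN92 replicate 1 feature 12 was at -0.20, and under median centring feature 9 was at -0.19. In the sample channel alone, features 8 and 10 turned direction, at -0.13 and -0.44. With the fixed replicate block, feature 8 passed with an adjusted p of 0.0450, and it was the 1 feature that did. Its adjusted p was 0.114 with that block as a random effect and 0.317 with the image folder as a block. Feature 6 was above background on 3 of 3 unstimulated KN92 arrays and not above it on any array of the other 5 groups. Its quantile-normalized log2 Cy3 signal parted them less clearly. It was 10.01, 9.77 and 9.10 on the former, the last on replicate 3, whose labels conflict. The highest of the others was 9.72, on stimulated KN92 replicate 2. Against the dimmest measurable signal of the arrays not above background, feature 6 was at least 1.19-fold higher in unstimulated KN92 than in unstimulated KN62 fibers (adjusted p 0.476). The latter include replicate 1, an array with a differing reference. No fold can be given against stimulated KN92 or unstimulated KN93 fibers.

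In fibers with KN93, stimulation is read under an inhibitor of the CaMK pathway. No feature passed by limma, and 2 had an unadjusted p under 0.05. Feature 7 was the lowest at a log2 change of -0.79 (SE 0.28, adjusted p 0.138), with means of 0.24 ± 0.11 (n = 3) and -0.55 ± 0.59 (n = 2). Within the 2 image folders its difference was -0.31 and -1.34. The larger one comes from the KN93 replicate 3 pair, at 0.37 unstimulated and -0.97 stimulated, both among the 4 arrays with a differing reference. On the KN62 replicate 1 pair, which has it too, feature 7 was at 0.21 and 0.37. The low value is thus not shared by these arrays. Without stimulated KN93 replicate 3 the change of feature 7 was -0.38, and without all 4 arrays with a differing reference it was -0.31. Each of these fits leaves 1 stimulated KN93 array, the one with the moved grid. From the deposited ratios, which follow the unmoved grid on that array, the change of feature 7 was 0.88. It was -0.10 without the columns in doubt, where replicate 3 is the 1 stimulated KN93 array left. Feature 4, measured on only 1 stimulated KN93 array, was at -0.71 (SE 0.58). Feature 8 was the highest at 0.45 (SE 0.26) and feature 15 was at 0.35 (SE 0.17). Without stimulated KN93 replicate 3, features 8 and 15 were at 0.09 and 0.51, and without replicate 1 at 0.81 and 0.19. Without all arrays in doubt, where the lone replicate 3 is left, features 7 and 8 passed with an adjusted p of 0.0147 and 0.0441. In the sample channel alone, features 4 and 8 turned direction, at 0.85 and -0.12. Features 7 and 9 passed with the experiment as a random replicate block, with an adjusted p of 0.0438 and 0.0336, and also with the image folder as a random block, at 0.0326 and 0.0230. With the replicate block or the image folder as a fixed block, 0 features passed, and features 7 and 9 had an adjusted p of 0.0529 each with the first and 0.127 each with the second. Feature 7 passed without stimulated KN93 replicate 1 (log2 change -1.21, adjusted p 0.0402), where the 1 stimulated KN93 array left is replicate 3, which is assumed to vary like the other groups.

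In fibers with KN62, the other inhibitor, 0 features passed by limma and 0 had an unadjusted p under 0.05. Feature 14 was the lowest of the 22, at a log2 change of -0.53 (SE 0.25, adjusted p 0.927), and feature 20 was at -0.17 (SE 0.25). Without stimulated KN62 replicate 2, whose labels conflict, feature 14 was at -0.28, and without all arrays in doubt at -0.06. With the image folder as a block it was at -0.89. That value rests on the 1 folder holding both states with KN62, where stimulated replicate 2 is set against 1 unstimulated array. Feature 20 ranged from -0.40 to 0.07 when 1 array at a time was left out. Feature 2 was the highest of those above background in both groups, at 0.21 (SE 0.79), followed by feature 10 at 0.20 (SE 0.19). Feature 2 ranged from -0.72 to 1.14 and feature 10 from 0.07 to 0.30 when 1 array at a time was left out. In the sample channel alone feature 2 was at -0.11, and from the deposited ratios at -0.38. With the sign of stimulated KN62 replicate 3 turned, feature 2 was at -0.01, and features 17 and 10 were the highest at 0.28 and 0.26, so the order is not settled. For the replicate 3 pair of this compound, the deposited ratios do not follow the scans filed under the same labels, so the stimulation state of those scans is in doubt. Without that pair the count was again 0.

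**Figure D3:**
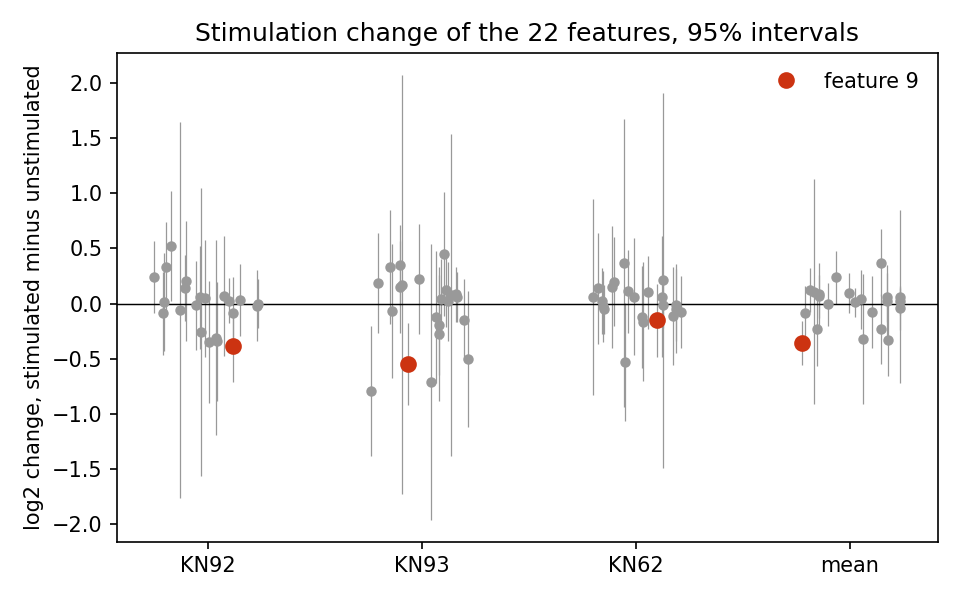
Log2 change from unstimulated to stimulated fibers of the 22 features in KN92, KN93, KN62 and their mean, with 95% intervals; points are spread sideways for legibility. Feature 9 (red) lies at -0.38, -0.55, -0.15 and -0.36.

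The next question was whether an inhibitor alters the response to stimulation. The difference of stimulation effects was tested between each pair of compounds, and limma called 0 features in each. An unadjusted p under 0.05 occurred for 1 feature in KN93 minus KN92, 0 in KN62 minus KN92 and 1 in KN93 minus KN62. Feature 7 was the lowest in KN93 minus KN92, at -0.84 (95% interval -1.64 to -0.05, adjusted p 0.876), and in KN93 minus KN62, at -0.85 (-1.65 to -0.06, adjusted p 0.820). With the sign of stimulated KN62 replicate 3 turned, the latter was -0.68, with feature 12 next at -0.62. Feature 15 was the highest in KN93 minus KN92 at 0.43 (-0.06 to 0.93). In KN62 minus KN92, feature 12 was at 0.50 (-0.29 to 1.28) and feature 8 at -0.38 (-1.09 to 0.33). With the sign of stimulated KN62 replicate 3 turned, these were 0.46 and -0.355, and feature 20 was the lowest at -0.57. When 1 array at a time was left out, these values of features 15, 12 and 8 ranged from 0.27 to 0.59, from 0.29 to 0.61 and from -0.58 to -0.17. Feature 7 ranged from -1.26 to -0.42 in KN93 minus KN92 and from -1.27 to -0.44 in KN93 minus KN62. Its values nearest 0 came without stimulated KN93 replicate 3. Feature 12 in KN62 minus KN92 turned direction with the deposited ratios, at -0.38 (-0.215 without the columns in doubt). Feature 8 there was at -0.06 without all arrays in doubt. The effects on feature 9 differed by -0.17 (-0.66 to 0.33) between KN93 and KN92 and by 0.23 (-0.24 to 0.70) between KN62 and KN92. Between KN93 and KN62 they differed by -0.40 (-0.89 to 0.10), and by -0.53 to -0.27 with 1 array left out. Leaving out 1 array at a time moved the first from -0.29 to -0.07 and the second from 0.10 to 0.36, and from the deposited ratios the second was -0.41 (-0.13 without the columns in doubt). The 95% intervals had a median half-width of 0.61, 0.60 and 0.61 in KN93 minus KN92, KN62 minus KN92 and KN93 minus KN62, over the 17, 18 and 17 features above background on at least 1 array of every group compared. The interval stayed within 1 on the log2 scale for 12, 13 and 10 of these. It describes the change after loess, which returned a median of 0.76 and as little as 0.21 for a planted doubling, so it does not exclude a doubling of the RNA. Without all arrays in doubt (stimulated KN93 replicates 1 and 2, unstimulated KN92 replicate 3, stimulated KN62 replicate 2 and both KN62 replicate 3 arrays), feature 7 passed in KN93 minus KN62 with -1.66 and an adjusted p of 0.0216. In that fit stimulated KN93 and stimulated KN62 fibers keep 1 array each, replicate 3 and replicate 1, both with the differing reference. Their spread is taken from the other groups, which these lone arrays are assumed to vary like. Without the 4 arrays with a differing reference, feature 7 was at -0.32 in KN93 minus KN62 and at -0.36 in KN93 minus KN92. That fit also keeps 1 stimulated KN93 array, the one with the moved grid. From the deposited ratios it was at 1.83 and 1.08, but 1 of the 2 stimulated KN93 arrays is on the unmoved grid there. Without the columns in doubt, where replicate 3 is the 1 stimulated KN93 array left, it was at 0.47 and 0.10.

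At rest, the compounds were compared in unstimulated fibers, 3 arrays each. No feature passed by limma in KN93 minus KN92, KN62 minus KN92 or KN93 minus KN62, with 1, 2 and 0 features at an unadjusted p under 0.05. With KN93 against KN92, feature 12 was at 0.54 (95% interval -0.01 to 1.10) and feature 2 at -0.51 (-2.22 to 1.19). Both rest on unstimulated KN93 replicate 3, an array with a differing reference, with log2 ratios of 1.26 and -1.23. On the other arrays of that set feature 12 was at 0.03, 0.15 and 0.68. Without the 4 such arrays features 12 and 2 were at 0.17 and -0.08. Feature 21 was at -0.37, -0.40 and -0.11 on the unstimulated KN92 arrays. It was at -0.02, 0.03 and 0.30 with KN93 and at 0.46, -0.03 and -0.05 with KN62, so higher on each array. The highest value with each inhibitor was on the array with a differing reference. With KN62 against KN92, feature 8 was at 0.54 (0.04 to 1.04, adjusted p 0.410), feature 21 at 0.42 (0.10 to 0.75, adjusted p 0.326) and feature 2 at -1.17 (-2.87 to 0.53). The low value of feature 2 with KN62 lies in replicate 1, one of the arrays with the brighter reference. Without the 4 arrays these values were 0.33, 0.26 and -0.24. With KN93 against KN62, feature 2 was at 0.66 (-1.05 to 2.36) and feature 8 at -0.29 (-0.80 to 0.21), and without the 4 arrays at 0.16 and -0.16. After loess, the intervals stayed within 1 on the log2 scale for 16 of 18, 17 of 19 and 17 of 18 features above background on at least 1 array of both groups.

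Under stimulation, limma called 0 features in KN93 minus KN92 and 0 in KN62 minus KN92, with 2 at an unadjusted p under 0.05 in each. With KN93, feature 7 was at -0.75 (95% interval -1.34 to -0.16, adjusted p 0.376) and feature 14 at 0.62 (0.02 to 1.22, adjusted p 0.469). With KN62, feature 12 was at 0.63 (0.08 to 1.19, adjusted p 0.314), feature 9 at 0.43 (0.10 to 0.76, adjusted p 0.314) and feature 2 at -0.90 (-2.60 to 0.80). Without stimulated KN62 replicate 1, which has a differing reference, feature 2 was at 0.03. After loess, the intervals stayed within 1 on the log2 scale for 12 of 17 and 15 of 18 features above background on at least 1 array of both groups. The values of feature 7 on the 2 stimulated KN93 arrays were -0.13 and -0.97, the latter on replicate 3, one of the arrays with a differing reference. On the other such arrays feature 7 was at 0.37, 0.21 and 0.37. Without the arrays in doubt, where replicate 3 is the 1 stimulated KN93 array left and is assumed to vary like the other groups, feature 7 passed at -1.17 with an adjusted p of 0.0187. Without replicate 3, which leaves the other stimulated KN93 array alone, it was at -0.33. From the deposited ratios feature 7 was at 1.34. Without the columns in doubt, which leaves replicate 3 as the 1 stimulated KN93 array, it was at 0.36.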

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

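The tests of the reference and sample channels for features 2 and 6 were chosen after the results were seen. So was the test of exchanged files. The tests of the feature called in the mean over compounds were aimed at it after the main fit had called it. The remaining tests were fixed before the results were seen. Signal was present in 12 spots that the deposited ratios leave out. A set of 6 spots, numbered 24 here, was above background on 17 of 17 arrays, with a median Cy3 signal of 2632 against a background of 1374. Another set, numbered 23, was above background on 12 of 17 arrays, with 1649 against 1343. No group held enough arrays for a test of single outlying samples within the group.

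Feature 9 was lower in stimulated fibers in the mean over compounds. In the sample channel alone its change was -0.40, with a 95% interval from -0.77 to -0.04 and an adjusted p of 0.381 by limma. For the mean over compounds, the interval argues against the reference channel as the whole cause. For KN62 it does not: log2 Cy3 rose in replicate 1 (13.49 to 13.79) and replicate 2 (13.83 to 14.01). It fell in replicate 3 (13.79 to 13.05), the pair whose stimulation state is in doubt. Without any 1 array the change of the log2 ratio stayed at or below -0.32, which argues against a single array. The loess step stays open: under median centring the change was -0.19, with an interval from -0.44 to 0.06 that holds both no change and all of the change seen. Chance was not excluded either, since 8 of 100 splits of the arrays within compounds gave as many calls (the real one included), with 3 in the highest other split against 1 in the real one; of the 6 that part as many experiments, the real one alone reached 1.

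On both KN62 replicate 1 arrays feature 2 lay at -2.87 and -2.66 where the other arrays had a median of 0.06. Its reference channel was brighter than on the other arrays by a mean of 3.12 on the log2 scale, and its sample channel differed by 0.14, which argues against a dimmer sample and is consistent with a reference that held more of this RNA on these arrays. Feature 6 was also low there, but its reference excess of 0.81 and its sample difference of -0.51 leave both channels open, since it was not above background in Cy3. The design names no biological group for this pattern, so no biological explanation was tested.

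The deposited ratios of the KN62 replicate 3 pair depart from the scans. A plain exchange of the 2 arrays' files would make each column follow the other scan. The unstimulated column did, at 0.05, but the stimulated column differed from the unstimulated scan by 0.397, above the highest of the other 16 samples at 0.105. An exchange with a scan outside the 18 stays open, and no biological explanation was tested.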

How the results depend on the processing

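The signal mean, the unmoved grid, the repeated scan as 2 replicates, the turned sign, the sets of arrays in doubt, those with a differing reference and the deposited ratios without the columns in doubt were chosen after seeing the data. The count of 1 feature for the mean of 3 compounds was 0 with no background correction, with subtraction, median centring, the sample channel alone, the median of spots and the deposited ratios. It was also 0 without the 2 arrays with conflicting labels, with the image folder as a block, with the signal mean, with the unmoved grid, without the KN62 replicate 3 arrays, without the 4 arrays with a differing reference and with the deposited ratios less the columns in doubt. It was 2 with the replicate block, fixed or random, and 0 to 1 when leaving out 1 array at a time. Feature 9 was lower in all 40 of these fits, from -0.51 to -0.19, and past the threshold in 14 of them, with an adjusted p from 0.0073 to 0.512. The deposited ratios are not centred alike: the median change of all features in this comparison was 0.21 there and 0.02 in the main setting. The replicate block gave 1 feature in KN92, its random form 2 in KN93, and neither changed another count. The count for KN93 was 2 with the image folder as a random block, 1 with the repeated scan as 2 replicates, 2 without all arrays in doubt and 0 to 1 when leaving out 1 array. Without all arrays in doubt, the difference of stimulation effects between KN93 and KN62 and the comparison of stimulated KN93 with KN92 fibers gave 1 each. The count for the mean was then 1 as well, but the feature was 8, not 9. The causes were not tested, except that these fits hold fewer arrays. For the other 7 comparisons, each count stayed at 0 under every alternative that could be run. Fixed blocks give no value for differences between compounds at rest or under stimulation. Centring on housekeeping genes and the gene list tests were not run, for want of gene names. Splits of the 6 arrays of a 3 against 3 comparison number 10, too few for a share under 0.05: 10 of 10 reached the real count of 0 in KN92 and in KN62 stimulation, in the 3 comparisons at rest and in stimulated KN62 minus KN92, with 3 calls in the highest other split for KN62 stimulation and 0 for the others. For the difference between KN62 and KN92, 100 of 100 splits reached the real count of 0 and the highest other gave 1. Every split reaches a real count of 0, so the splits cannot test any of these comparisons. Signal over background limits features 3 and 13, which had no array above background.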

Other observations

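Whether the 3 compounds share 1 response to stimulation was tested by correlating the stimulation changes of the 22 features between compounds, which share no arrays; this test was fixed before its result was seen, and its alternatives were chosen after. Pearson's r was 0.50 between KN92 and KN93 (2-sided permutation p 0.0177, adjusted 0.053 over 3 pairs), 0.16 between KN92 and KN62 (p 0.470, adjusted 0.509) and 0.15 between KN93 and KN62 (p 0.509, adjusted 0.509). Spearman's rho was 0.34, -0.02 and 0.26 in the same order, with an adjusted p of 0.361, 0.920 and 0.361. Between KN92 and KN93, rho was 0.63 under median centring (adjusted permutation p 0.0062) and 0.67 without all arrays in doubt. Without the 4 arrays with a differing reference it was 0.26 (adjusted permutation p 0.362). These are correlations across features, which are not independent replicates. All 3 values of r were above 0, but none passed after adjustment. Between KN92 and KN93, r passed under median centring (0.51, adjusted p 0.0441) and without all arrays in doubt (0.55, adjusted p 0.0274), and fell to 0.21 (adjusted p 0.545) without the 4 arrays with a differing reference. With the sign of stimulated KN62 replicate 3 turned, r was 0.31 between KN92 and KN62 and 0.41 between KN93 and KN62, with an adjusted p of 0.168 and 0.0848. Without both KN62 replicate 3 arrays the same pairs had 0.05 and 0.24. The test does not decide whether a shared response exists.

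Feature 8 was higher in all 3 stimulated KN92 arrays than in all 3 unstimulated ones, a separation that chance gives in 10% of cases for one feature. Its stimulation difference was positive in each image folder that held both states, at 0.34 and 0.76 for KN92, 0.17 and 0.66 for KN93 and 0.17 for KN62. The 0.76 uses unstimulated KN92 replicate 3 and the KN62 value uses stimulated replicate 2, whose labels conflict on the stimulation state. The 0.66 comes from the KN93 replicate 3 pair, which has a differing reference. In the sample channel alone the direction turned, with changes of -0.13 for KN92, -0.12 for KN93 and -0.22 for KN62, so the rise in the ratio is not seen in that channel. It was singled out after its values were seen.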
